A study of Drosophila melanogaster with 4 samples.

How the data were processed

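ChIP-seq was performed on head nuclei of mixed adult Drosophila melanogaster (Oregon-R, wild type), with 2 immunoprecipitations for HP1b and 2 inputs. Per the labels' protocols, heads were collected by sieving, the tissue was homogenized and fixed with formaldehyde, and chromatin was sheared by sonication before immunoprecipitation. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The genome build was FlyBase release 5, per the file headers. The cluster caller, its threshold, the read filters and the way each input was used are not given in the sources used here.

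Each list gives the sequence, start and end of every cluster in base pairs and a score per cluster, as deposited by the authors. The formula and scale of the authors' score are not given in the sources used here. The score was above 0 in every row typed as enrichment and below 0 in the 12 rows of the combined list typed as depletion. It was used to rank, filter or describe clusters within a list. Between replicates it was compared by rank and, for matched clusters, by correlation, where Pearson's r takes the scale of the score as linear and Spearman's rho does not. Clusters were listed per ChIP sample for replicates 1 and 2. The third list carries the name of a replicate set, and how the replicates were combined for it is not given in the sources used here. The inputs enter no comparison here because no values of their own were used. The files hold no read counts, so depth is unknown and neither counting intervals nor detection floors can be given for coverage. The precision of each value is therefore given as the spread of 2 replicates.

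Positions are 1-based. A single cluster of the combined list on 3R began at position 0 and was set to begin at 1. Coverage is the share of a sequence's length, taken from the file headers, that lies under clusters, and clusters within a list did not overlap. Samples were grouped by their titles. Overlap of replicate lists was counted at 1 bp and tested against 1000 random placements of the other list within each sequence with widths kept (one-sided). Bins of 1 Mb were counted from the centromere end of each long arm, which is the end of 2L, 3L and X and the start of 2R and 3R. Intervals and placements were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The overlap test was checked on simulated lists of 6687 clusters. With 90% of the clusters kept and moved by less than the narrowest cluster width, 100% of the kept clusters were recovered, which so small a move makes certain. Of 20 unrelated simulated lists, 0 gave p under 0.05. The unrelated lists were placed by the same random rule as the test, so this check does not cover lists that are unevenly spread.

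The comparisons, the alternatives and the regions to name were fixed before the data were examined, except where stated. The 5 kb width class, the extreme bins and the positions given for chromosome 4 were chosen after the values were seen. The regions named are the 10 of highest score and the 10 widest of the combined list, among those on 2L, 2R, 3L, 3R, 4 and X with at least 50% of their length under clusters of each replicate. The alternatives were a stricter overlap, the higher-scoring clusters of each list, the combined list, a width minimum, other bins, circular shifts and each replicate alone. Genic position and 16 gene lists fixed beforehand were not analysed, since the gene table at hand is of genome release 6 and coordinates were not converted between releases.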

Results

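Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map HP1b in nuclei from heads of adult fruit flies of the wild-type strain Oregon-R. HP1b is a paralog of heterochromatin protein 1, a family of chromatin proteins that carry a chromodomain and a chromoshadow domain. The series held 4 samples: 2 immunoprecipitations with the HP1b antibody Q4114 (replicates 1 and 2) and 2 input samples of chromatin without immunoprecipitation, each named as the input of the like-numbered ChIP sample. Values came from 3 lists of enriched regions, called clusters here. Replicate 1 had 6687 clusters over 18.4 Mb, replicate 2 had 6471 clusters over 17.7 Mb, and a combined list for the replicate set had 7807 clusters over 21.2 Mb. The lists give no read totals, so the depth of each library is unknown here. Input signal entered only as far as the authors used it in calling clusters, and no background level in the inputs could be given.

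HP1b clusters lay mostly on the assembled chromosome arms, and the fourth chromosome and X carried the most cluster sequence for their length. Clusters covered 20.97% ± 1.76 (SD, n = 2) of chromosome 4, the small dot chromosome known for its heterochromatic character. They covered 17.8% ± 0.420 (SD, n = 2) of X and 13.8% ± 0.458 (SD, n = 2) of the combined length of the 4 long autosomal arms. Among those arms, 2R stood highest at 15.6% ± 0.551 (SD, n = 2), while 2L had 13.2% ± 0.380, 3L 13.3% ± 0.417 and 3R 13.6% ± 0.487 (SD, n = 2 each). The 6 sequences assigned to heterochromatin in the assembly (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) were covered over 2.75% ± 0.276 (SD, n = 2) of their length. Unplaced sequence U was covered over 1.20% ± 0.00723 (SD, n = 2), and the 29.0 Mb of Uextra held no cluster in any list.

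**Figure D1:**
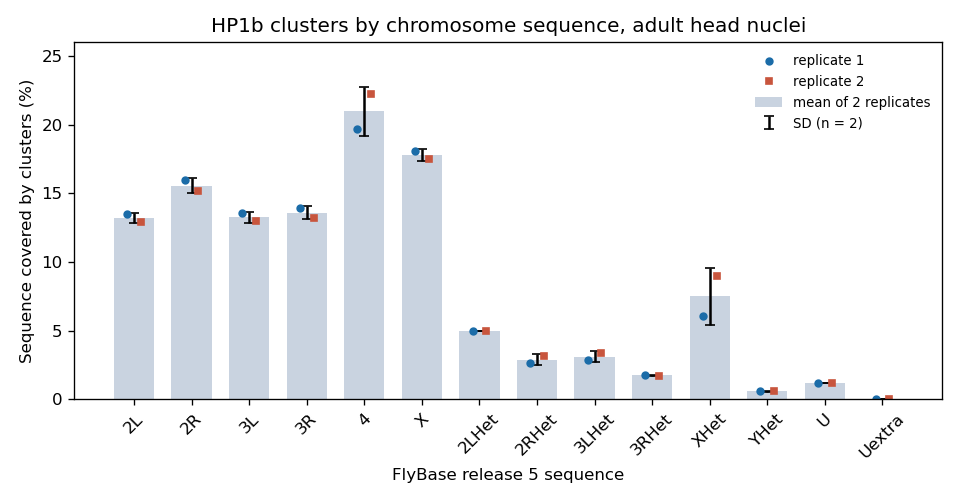
Share of each FlyBase release 5 sequence covered by HP1b clusters (y axis, %), by sequence (x axis); bars are the mean of 2 ChIP replicates, error bars the SD, circles replicate 1 and squares replicate 2. Chromosome 4 (20.97%) and X (17.8%) stand above the long autosomal arms, and the heterochromatin sequences lie below all arms.

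The ratio of X to autosomal coverage was 1.28 in replicate 1 and 1.29 in replicate 2, and that of chromosome 4 was 1.39 and 1.64. X exceeded each of 2L, 2R, 3L and 3R in both replicates, by more than the spread between replicates. Both the number and the mean width of clusters differed: X carried 61.3 ± 1.10 clusters per Mb with a mean width of 2900 ± 16.2 bp, against 51.8 ± 1.34 per Mb and 2675 ± 19.2 bp on the long autosomal arms (SD, n = 2). Median widths were closer. On X they were 2356 bp in replicate 1 and 2309 bp in replicate 2, against 2273 to 2323 bp and 2244 to 2301 bp on the separate autosomal arms. Clusters of 5 kb or wider made up 9.59% ± 0.341 of X clusters and 5.07% ± 0.0243 of clusters on the long autosomal arms (SD, n = 2). The X and autosomal values of a replicate come from the same library, and X was higher in 2 of 2 replicates. No test was made across the replicates. The labels do not state whether the replicates came from separate fly collections, so the spread may be technical.

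Wide clusters were frequent on chromosome 4 and on 4 of the 6 heterochromatin sequences. On chromosome 4, 20.8% ± 3.81 of clusters were 5 kb or wider, and on the 6 heterochromatin sequences pooled 21.3% ± 1.89 (SD, n = 2). The separate heterochromatin sequences differed and held few clusters: XHet and YHet had none of 5 kb or wider in either replicate, and 3RHet had 3 of 12 in replicate 1 and 5 of 8 in replicate 2. Their density differed: chromosome 4 carried 60.7 ± 1.046 clusters per Mb, and the heterochromatin sequences 7.81 ± 0.381 per Mb (SD, n = 2). The first cluster on chromosome 4 began at position 61181 in replicate 1 and 61076 in replicate 2, and the last ended 3102 and 3221 bp from the end of the sequence. The widest chromosome 4 cluster of replicate 1 spanned 950418 to 958844, and that of replicate 2 spanned 1045850 to 1054769. The longest stretch of chromosome 4 without a cluster between clusters ran from 725638 to 807229 in replicate 1 and from 719505 to 807172 in replicate 2. XHet was covered over 6.04% in replicate 1 and 8.95% in replicate 2, 2LHet over 4.99% ± 0.00709 (SD, n = 2), and YHet held 1 cluster in each replicate. 2LHet held 4 clusters in replicate 1 and 5 in replicate 2, so its small SD says little about its precision. Coverage of the heterochromatin sequences is relative to their full length, including any assembly gaps, whose extent was not determined here. Chromosome 4 and the heterochromatin sequences together held 2.29% of replicate 1 clusters and 2.41% of replicate 2 clusters, so their values rest on few clusters.

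The distribution along the long arms was uneven, and cluster coverage was low next to the centromere on X and 3L. The last 1 Mb of 3L before the centromere was covered over 2.82% ± 0.892, against 13.7% ± 0.473 for the rest of the arm, and the last 1 Mb of X over 6.09% ± 0.222, against 18.3% ± 0.429 (SD, n = 2). The first 1 Mb of 2R was covered over 11.5% ± 0.624, against 15.8% ± 0.609 for the rest of that arm (SD, n = 2). The last 1 Mb of 2L had 11.8% ± 1.11 and the rest of 2L 13.3% ± 0.448, a difference that was 2.59 percentage points in replicate 1 and 0.390 in replicate 2. On 3R the direction was opposite in both replicates, with 14.5% ± 0.422 in the first 1 Mb and 13.6% ± 0.490 beyond it (SD, n = 2). Over the 5 arms the centromere-proximal 1 Mb had 0.598 times the coverage of the rest in replicate 1 and 0.665 times in replicate 2.

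**Figure D2:**
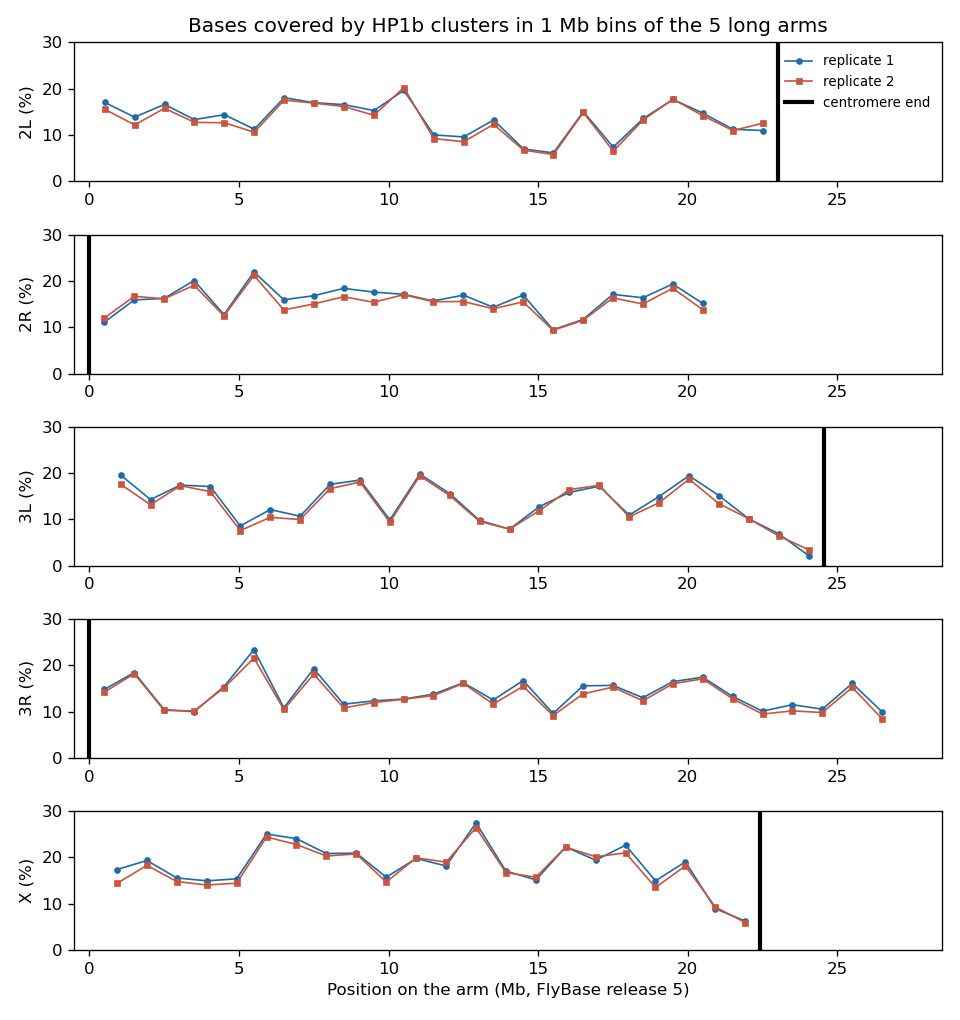
Bases covered by HP1b clusters (y axis, %) in full 1 Mb bins along the 5 long arms (x axis, Mb, FlyBase release 5), with circles for replicate 1, squares for replicate 2 and a thick line at the centromere end. Coverage falls toward the centromere on 3L and X, and the bins of both replicates follow each other closely.

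The most densely covered 1 Mb bins lay on X, among bins singled out after their values were seen. The bin from 12422828 to 13422827 of X was covered over 26.9% ± 0.736, the bin from 5422828 to 6422827 over 24.7% ± 0.456 and the bin from 6422828 to 7422827 over 23.4% ± 0.889 (SD, n = 2). The next was on 3R, from 5000001 to 6000000, with 22.4% ± 1.28 (SD, n = 2). Away from centromeres, the lowest coverage was on 2L, where the bins from 15011545 to 16011544 and from 14011545 to 15011544 had 5.99% ± 0.254 and 6.89% ± 0.177 (SD, n = 2). Across the 117 full bins, coverage in the replicates correlated with Pearson's r = 0.985 and Spearman's rho = 0.980. These are correlations across neighbouring bins, which are not independent samples, so no p-value is given.

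The strongest single region by the authors' score lay on 2R from 11734362 to 11737183, with a score of 5.15 in the combined list, and it ranked 1 in the list of each replicate. It was followed by 3L from 12564413 to 12566886 (score 4.39), which ranked 2 in each replicate, and by 3R from 22013398 to 22015986 (score 4.25), which ranked 5 in replicate 1 and 3 in replicate 2. The fourth was 2R from 2548402 to 2552436 (score 4.19). Of the 10 regions of highest score that both replicates covered, 3 lay on 3L, 2 each on 2L, 2R and 3R, and 1 on X, from 16732888 to 16735466 (score 4.00). The remaining regions were 3L 15974881 to 15977351, 3R 9226156 to 9230263, 2L 8996320 to 8998723, 3L 4552460 to 4555494 and 2L 7798716 to 7801501, with scores from 3.93 to 4.01. These 10 regions were 2.40 to 4.11 kb wide. The scale of the score is not given in the sources used here, so for these regions it serves only to rank them within a list.

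The widest regions were a different set, with none shared between both sets of 10. Of the 10 widest regions that both replicates covered, 6 lay on X, 2 on 2R and 2 on 3R. The widest spanned 22.7 kb of X, from 8779736 to 8802437, and the next 21.6 kb of X, from 7584459 to 7606100. The 3R region from 5901559 to 5921422 was 19.9 kb wide and the 2R region from 17583430 to 17603146 was 19.7 kb wide. The others on X began at 14100648, 11480209, 3564523 and 6587405 and were 13.5 to 17.1 kb wide, and those at 6434214 on 2R and 10102655 on 3R were 14.1 and 13.3 kb wide. Their scores in the combined list ranged from 1.21 to 2.25. That these lie below all of the 10 regions of highest score follows from the sets sharing no region. Across all clusters of the combined list, score rose with width (Spearman's rho 0.739). The region at 8779736 was a single cluster in the combined list and 3 clusters in each replicate, so a width depends on where clusters were split. No gene is named for any region, because the gene table at hand is of genome release 6 and the lists are on release 5.

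**Figure D3:**
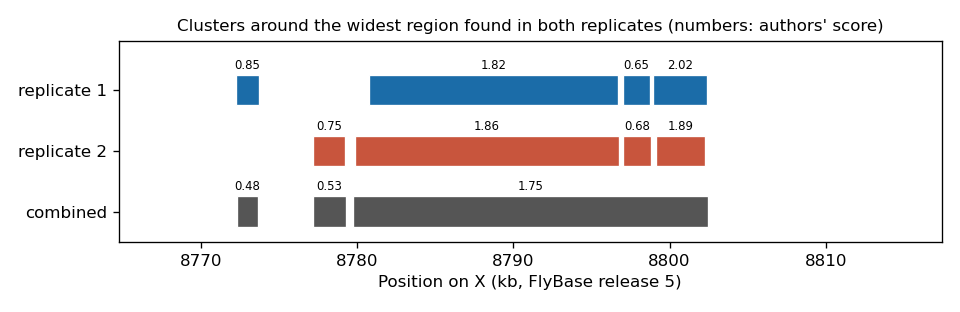
Clusters of replicate 1, replicate 2 and the combined list (rows) around the widest region on X (x axis, kb, FlyBase release 5), with the authors' score above each cluster. The combined list joins into 1 cluster of 22.7 kb what each replicate lists as 3 clusters.

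The replicates placed most clusters at the same sites. Of the replicate 1 clusters, 5999 of 6687 (89.7%) overlapped a replicate 2 cluster by at least 1 bp, and 6003 of 6471 replicate 2 clusters (92.8%) overlapped a replicate 1 cluster. Random placement of the other list within each sequence gave 24.6% and 25.4% on average and at most 26.4% and 26.9% in 1000 placements (one-sided permutation test, p = 0.001 for each, the smallest these placements can give). The lists shared 16.3 Mb, a Jaccard index of 0.824 against 0.0756 for random placement (p = 0.001, same permutation test). No cluster had the same start and end in both lists. Clusters without a counterpart had low scores: their median was 0.465 in replicate 1 and 0.453 in replicate 2, against 1.15 and 1.16 for those with a counterpart in the same list. Among 5705 clusters that matched in pairs, the scores of the replicates correlated with Pearson's r = 0.964 and Spearman's rho = 0.949. Within the long autosomal arms rho was 0.950, on X 0.944, on chromosome 4 0.940 (60 pairs) and on the heterochromatin sequences 0.879 (52 pairs), all across clusters, which are not independent samples.

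The replicates differed in a way that followed the sequence. Replicate 1 covered more of each long arm, 14.9% of the 5 arms together against 14.3% in replicate 2. The arms were not uniform in this. Replicate 2 was higher in 5 of 10 bins in the first 2 Mb from the centromere, against 12 of 112 other bins. Replicate 2 covered more of chromosome 4, 22.2% against 19.7%, and more of the heterochromatin sequences together, 2.95% against 2.55%. Of the separate heterochromatin sequences, 2RHet, 3LHet and XHet were higher in replicate 2, by 0.551, 0.539 and 2.91 percentage points, while 2LHet, 3RHet and YHet differed by less than 0.1 percentage points. With a single list on each side, this difference has no replicate check.

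The combined list held 5857 of 7807 clusters (75.02%) that overlapped clusters of both replicates, 644 that overlapped replicate 1 only, 444 that overlapped replicate 2 only and 862 (11.04%) that overlapped neither. It held 99.3% of replicate 1 clusters and 99.8% of replicate 2 clusters. Clusters found in both replicates had a median score of 1.12 and a median width of 2520 bp, and those in neither had 0.351 and 1273 bp. Not all clusters in neither were weak, as their highest score was 3.73. Of the clusters in neither, 456 (52.9%) were narrower than 1301 bp, the narrowest cluster of the replicate lists. On chromosome 4, 27 of 117 combined clusters (23.1%) were in neither replicate list, and on X 210 of 1656 (12.7%).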

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

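The combined list holds 12 regions typed as significant depletion of HP1b signal, a kind of region that enters no comparison above. They lie on the autosomal arms, 3 on 2L, 2 on 2R, 3 on 3L and 4 on 3R, and are 1507 to 1867 bp wide with scores from -0.110 to -0.00806. Of the 12, 10 overlap a cluster listed as enriched in at least 1 replicate, 5 such clusters in replicate 1 and 7 in replicate 2. The depleted region of 3R from 17233329 to 17235176 and that of 2L from 11828498 to 11830364 overlap an enriched cluster in both replicates. The scores of these 12 replicate clusters were low, 0.0748 to 0.365, at or below percentile 6.33 of their list, and none of them overlapped an enriched cluster of the combined list. The 10 overlapping regions are thus listed with opposite types in the lists, and no explanation was tested.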

How the results depend on the processing

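The overlap of the replicates kept its direction and p-value side under every score, sequence and shift alternative run. With the stricter overlap of 50% of cluster length, random overlaps were undercounted, with means of 0.193% and 0.0924% of replicate 1 clusters. No p-value is therefore used for it. The observed overlap over all these alternatives was 87.4% to 90.7% of replicate 1 clusters and 90.3% to 93.7% of replicate 2 clusters. The Jaccard index was 0.818 to 0.827 where it was computed. X and chromosome 4 stayed above the autosomal arms, and heterochromatin below, under all alternatives run, but the ratios moved. With the combined list they were 1.34 for X, 1.72 for chromosome 4 and 0.230 for heterochromatin. With the higher-scoring clusters of each list they were 1.50, 1.77 and 0.270, against 1.28, 1.52 and 0.199 for all clusters. Leaving out the 2 Mb next to each centromere, an alternative chosen after seeing the data, gave 1.338 for X. Clusters in both replicates made up 98.3% of the higher-scoring clusters of the combined list and, in another alternative added after seeing the data, 80.6% of combined clusters as wide as the replicate lists allow, so both the score and the narrow clusters bear on the 75.02%. The causes of the other moves were not tested. The centromere-proximal ratio moved by less than the spread of the replicates (0.624 with bins of 500 kb), and the correlation of scores was 0.949 with reciprocal overlap as with any overlap. Without replicate 1 or replicate 2 in turn, the ratios were 1.28 to 1.29 for X, 1.39 to 1.64 for chromosome 4, 0.180 to 0.218 for heterochromatin and 0.598 to 0.665 for the centromere-proximal 1 Mb, which with 2 replicates lie within 1 SD of the mean by construction. Coverage of the 13 separate sequences moved with the combined list in all 13 and with the higher-scoring clusters in 12. Leaving out lower-scoring clusters can only lower coverage, and the combined list covers more sequence than either replicate list, so these moves say little. The minimum of 1 kb removed no cluster of a replicate list and tests nothing. Overlap cannot be computed without either replicate. The genic and gene list alternatives were not run, as no annotation of release 5 was used here. No paired analysis was possible because the inputs have no values of their own here. Unknown read depth limits any statement on weak clusters.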

Other observations

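The X alternative without centromere-proximal sequence, the alternative of combined clusters as wide as the replicate lists allow, the placements within 1 Mb bins or without overlap, the ratios of single arms and the split of rank changes by width were tests chosen after the result was seen, and the other tests were set before their values were computed. The runs and the stretches named here were chosen after their values were seen. HP1b clusters occurred in groups along the chromosomes. The next cluster lay within 5 kb for 43.1% of clusters in replicate 1 and 42.8% in replicate 2, against 34.1% and 33.1% on average under random placement of the same widths (one-sided permutation test, p = 0.001 in each, the smallest 1000 placements can give). To test the splitting of single regions by the caller, clusters 1 kb or less apart were joined. The joined regions still had a neighbour within 5 kb more often than at random placement, 34.9% against 32.0% in replicate 1 and 35.0% against 31.1% in replicate 2 (same permutation test, p = 0.001 in each). Uneven density along the sequences raises this share too, and placement within the 1 Mb bin of each cluster or region gave p = 0.001 in each replicate for clusters and p = 0.002 and 0.001 for joined regions (one-sided permutation tests). These placements allow overlaps and short gaps that the lists or joined regions cannot have, so the size of the excess was taken from placements without overlap, with joined regions kept more than 1 kb apart. Within each sequence the excess was then 15.9 and 16.6 percentage points for clusters and 13.9 and 14.6 for joined regions in replicates 1 and 2, and within 1 Mb bins 14.4 and 14.98 for clusters and 12.6 and 13.3 for joined regions (one-sided permutation tests, p = 0.001 in each). Splitting at gaps above 1 kb and uneven density on a scale below 1 Mb were not tested and stay open. The longest joined regions of replicate 1 were a run of 5 clusters on X from 6222090 to 6253214 (31.1 kb) and a run of 4 on X from 3564611 to 3590538 (25.9 kb). In replicate 2 they were a run of 5 on 2L from 11987056 to 12013128 (26.1 kb) and a run of 4 on X from 3564514 to 3590346 (25.8 kb).

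Long stretches without clusters were shared by the replicates. On X the longest ran from 21504390 to 21844038 in replicate 1 and from 21505948 to 21844016 in replicate 2, about 339.6 and 338.1 kb. On 2R it ran from 2155863 to 2380818 and from 2160992 to 2380824. On 3R it began at 6242866 and 6242862 and was 204.2 and 220.5 kb long. On 2L and 3L the longest stretch lay at different places in the replicates.

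X carried more cluster sequence per length than the autosomal arms. The excess was not confined to lower-scoring clusters: among the higher-scoring clusters of each list the ratio was 1.51 in replicate 1 and 1.48 in replicate 2, above that for all clusters. The cut was the median score of the whole list. Median scores were higher on X than on the autosomal arms (1.17 against 0.999 in replicate 1, 1.16 against 1.04 in replicate 2). A general rise of scores on X would raise this ratio too, so an effect of the calling threshold is not excluded. Long regions confined to a few bins of X do not account for the excess. The median 1 Mb bin of X had 1.24 times the median autosomal bin in replicate 1 and 1.32 times in replicate 2. Wide clusters spread over many bins would raise that median too, so the ratio cannot decide on them. Clusters of 5 kb or wider made up 9.83% and 9.35% of X clusters in replicates 1 and 2, against 5.09% and 5.05% on the long autosomal arms. Their part in the excess was not tested. A lower copy number of X in a mixture of males and females, and how the authors scaled ChIP to input, could not be examined without read depth. The design gives no groups that bear on X, so no biological explanation was tested.

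The heterochromatin sequences carried few clusters for their length, while chromosome 4 carried many. Assembly gaps and repeats that hold no placed reads are a candidate explanation. Low coverage that extended into assembled arm sequence was set beforehand to argue against gaps alone. That holds only where the arm sequence itself lacks gaps and such repeats, which was not examined here. The centromere-proximal 1 Mb of the arms had 0.598 and 0.665 times the coverage of the rest in replicates 1 and 2, between the bounds set beforehand. The arms differed: the ratio was 0.156 and 0.258 on 3L and 0.335 and 0.329 on X, so low coverage extends into arm sequence there, but 0.685 and 0.781 on 2R, 0.809 and 0.970 on 2L and 1.06 and 1.07 on 3R. The tables leave this open, since neither gaps nor mappability of release 5 were examined here and chromosome 4 alone cannot stand for the other heterochromatin.

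Replicate 2 covered more of chromosome 4 and of the heterochromatin sequences and less of the long arms than replicate 1. The 5 long arms differed by -0.637 percentage points (replicate 2 minus replicate 1), chromosome 4 by 2.49 and heterochromatin by 0.391. If the lists differed only in whether whole borderline clusters were listed, shared clusters would keep their scores and widths. Borderline signal at the edges of shared clusters can change their width, so the comparison of shared clusters cannot decide on it. The 112 shared clusters of chromosome 4 and heterochromatin ranked a median of 8.61 percentile points higher in replicate 2. The 95% bootstrap interval over clusters was 6.44 to 10.5, which treats neighbouring clusters as independent. Of the 112, 97 ranked higher and 90 were wider. These sequences were singled out because replicate 2 covers more of them, and score rose with width in each list (Spearman's rho 0.743 and 0.745 across clusters). The rise in rank is therefore not independent of the coverage difference. It shows only that shared clusters differ too. Shared clusters of the long arms moved by a median of -0.386 points. Rank and width changed together, so a split by width class is not independent of the rank change. Within each class the clusters of chromosome 4 and heterochromatin stood above the long arms. Those not wider in replicate 2 moved by a median of 2.39 points (higher in 13 of 22) against -2.40 on the long arms, and those wider by 9.45 against 4.07. The class not wider is small, and these differences were not tested. The difference rests on 1 list per side. No other explanation was tested, and no values of the inputs were used here.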
